A study of Harpegnathos saltator with 32 samples.

How the data were processed

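Polyadenylated RNA was measured by strand-specific sequencing in central brains of the ant Harpegnathos saltator, with 1 brain per library, per the labels' protocols. Ants were injected in the head with dicer-substrate siRNA against Kr-h1 or with a GFP control siRNA, and brains were taken 10 hours later, per the labels. The protocol text writes the control as GRP, while the titles write GFP, and GFP is used here. The 32 libraries fall into 4 groups: 8 worker GFP, 7 worker Kr-h1, 9 gamergate GFP and 8 gamergate Kr-h1. The series' design text states that replicates were individual brains.

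The deposited values are FPKM (fragments per kilobase, scaled for depth) for 14001 genes, and the authors made them before deposit. The submitters' processing notes list bcl2fastq, STAR, featureCounts and DESeq2 with no version and no role. The genome build, the annotation and the factor behind the depth scaling are not given in the sources used here, so no coordinates are printed. Gene identifiers were matched to the symbols of the Harpegnathos RefSeq assembly Hsal_v8.6, used for names and gene span only. Of the identifiers, 13989 matched and 12 did not, and 4117 genes carried a symbol other than a number. Strand was kept in the libraries, but whether the counting used it is not given.

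Depth was read from the low values. Where reads are whole, the FPKM values of a gene are whole multiples of 1 step once libraries are put on 1 scale. A step was found for 12454 genes, 98.1% of the 12692 genes detected in at least 3 libraries, with a tolerance of 0.02 reads plus a term that grows with the value. With library scales jittered at random, the same search found a step for 2.0% of 500 genes. The 238 detected genes without a step were abundant, with a median of 104.1 FPKM. Recovered reads ranged from 4.50 to 12.95 M per library, with a median of 7.50 M. Even read numbers made up 55.1% of the nonzero values, so a recovered read is not certain to be an independent fragment.

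Tests used limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5), for the 9433 genes with FPKM of at least 1 in at least 7 libraries. All libraries entered 1 fit with 4 group coefficients and a batch term of 3 levels, and eBayes used a mean-variance trend. The levels were round 2 on run 200626, round 3 on run 200626 and round 2 on run 200508, from the description label. Round 2 gamergates were alone on run 200508, so caste and run can be separated only in round 3. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are on the log2(FPKM + 0.5) scale, which understates the change of low genes. Kr-h1 lay below the filter and was tested by an exact permutation of its mean log2 value within each caste and by limma without the filter.

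Simulated data with 200 of 9433 genes altered were used to test the fit. For workers, 71% of 1.5-fold and 87% of 2-fold changes were recovered. For gamergates, the shares were 80% and 92%, and for caste in GFP controls 55% and 86%. False calls were 10 of 168 in workers, 4 of 176 in gamergates and 11 of 152 for caste. The simulated noise was independent between genes and had the same spread in every library. In the real data genes moved together, with an estimated correlation of 0.867 among cytosolic ribosomal genes. The shares therefore test the fit and do not give its power in the real data.

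Gene lists were fixed before the data were examined as description patterns and fly symbols. The lists for fat body, muscle, haemocytes and retina were set as markers of other tissues that a dissected central brain could hold. The reference gives no descriptions, so members were picked by symbol later, before any list was tested. Of the 26 lists, 24 had at least 3 measured members and were tested with limma's camera at a preset correlation of 0.01, with adjustment over lists, and again with an estimated correlation. Genes named in the text follow a rule set before the data were examined: Kr-h1, the 10 named genes with the highest and the 10 with the lowest log2 fold change among those called, up to 5 per direction with the smallest p where fewer passed, up to 4 members of each called list, and a fixed panel. Panel members without a matching symbol are not reported. For caste-biased genes, round 3 controls gave the 200 genes with the highest and the 200 with the lowest moderated t for gamergate against worker. The knockdown change came from round 2 libraries, so that no library entered both.

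Alternatives covered the pseudocount, the filter, the scaling, the batch term, the libraries used, a replicate block, array weights, a robust variance model and each library left out. Added after seeing the data were fits to round 2 only, without the low-complexity libraries, without the 4 libraries with an array weight under 0.3, with each library's trend over gene span removed by loess, and limma voom on recovered reads. The caste-biased genes were also tested without the low-weight libraries and with the span trend removed, and the called lists and the correlations between effects without each library. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.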

Results

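Brain transcriptomes were compared between workers and gamergates of the ant Harpegnathos saltator, on day 10, 10 hours after siRNA against Kr-h1 or GFP. Gamergates are workers that have become reproductive. Kr-h1 encodes a zinc finger transcription factor that responds to juvenile hormone. There were 8 worker GFP, 7 worker Kr-h1, 9 gamergate GFP and 8 gamergate Kr-h1 libraries, each from a single brain. Recovered reads ranged from 4.50 M in gamergate Kr-h1 replicate 6 to 12.95 M in worker Kr-h1 replicate 6. Among 966 genes with a median of 5 to 20 scaled reads, 42.3% were listed at 0 in worker GFP replicate 4 and 26.1% in worker GFP replicate 5. No pair of libraries held identical values, and Spearman correlations within groups ran from 0.852 to 0.980.

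The targeted gene was examined first. Kr-h1 (LOC112589664) averaged 1.83 ± 2.28 FPKM (SD, n = 9) in gamergate controls and 0.443 ± 0.291 FPKM (SD, n = 8) in gamergates given Kr-h1 siRNA. Gamergate GFP replicate 1 was at 7.57 FPKM, and the other gamergate controls averaged 1.11 ± 0.806 FPKM (SD, n = 8). In workers Kr-h1 averaged 0.910 ± 0.701 FPKM (SD, n = 8) in controls and 0.438 ± 0.187 FPKM (SD, n = 7) after Kr-h1 siRNA. The difference of mean log2 values was -0.97 in gamergates (exact two-sided permutation p = 0.0105, adjusted over both castes 0.021) and -0.49 in workers (exact p = 0.0359, adjusted 0.0359). Without gamergate GFP replicate 1, the gamergate difference was -0.70 (exact p = 0.0145). These tests do not adjust for round and run. With the batch term, limma gave -1.02 ± 0.28 in gamergates (SE; unadjusted p = 0.00106, adjusted p = 0.0845) and -0.48 ± 0.30 in workers (SE; unadjusted p = 0.117, adjusted p = 0.466), so neither passed over all genes. Of the knockdown libraries, 7 of 8 in gamergates and 6 of 7 in workers lay below their control median. Read numbers were small, from 4 in gamergate Kr-h1 replicate 1 to 362 in gamergate GFP replicate 1. Within gamergates, the difference was -1.79 in round 2 (exact p = 0.0571) and -0.32 in round 3 (exact p = 0.0556). In workers it was -0.60 in round 2 (exact p = 0.143) and -0.30 in round 3 (exact p = 0.20, where 20 splits cannot give less than 0.1). The worker result missed 0.05 when any of worker GFP replicates 3, 4 and 5 or worker Kr-h1 replicates 1, 2, 3, 5, 6 and 7 was left out (exact p from 0.0579 to 0.0769), with a difference of -0.32 without worker GFP replicate 4. The difference of the knockdown effect between castes was -0.54 ± 0.41 (SE) and missed the threshold (limma adjusted p = 0.419).

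**Figure D1:**
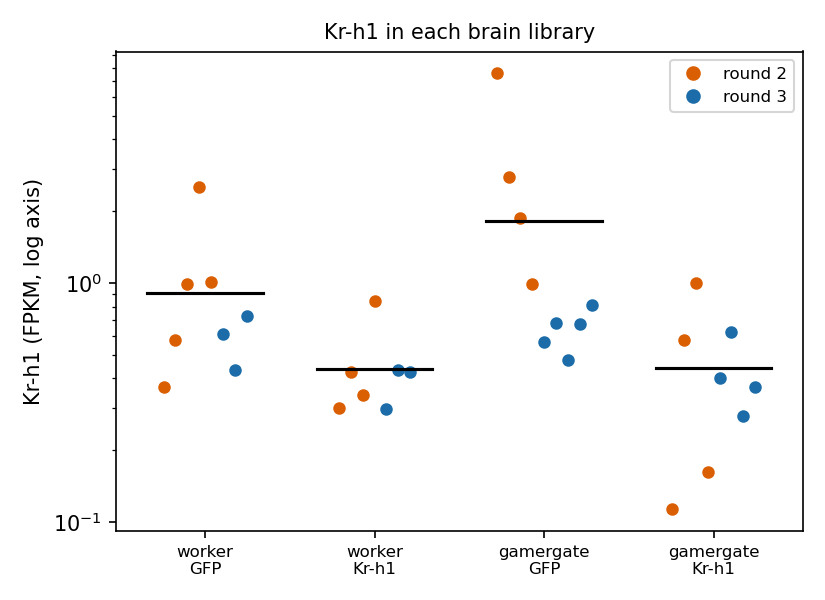
Kr-h1 in FPKM (log axis) in each library of the 4 groups, coloured by experiment round; black lines are group means. Gamergate controls of round 2 reach 7.57 FPKM, and knockdown libraries lie between 0.114 and 1.01 FPKM.

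The first comparison asks which genes differ with Kr-h1 knockdown in workers. Several muscle genes lay below 0: Mlc2 (LOC105192051), a myosin light chain, averaged 21.1 ± 14.6 FPKM (SD, n = 8) in controls and 5.01 ± 4.62 FPKM (SD, n = 7) after knockdown, a log2 difference of -2.01 ± 0.52 (SE; limma adjusted p = 0.144). Myofilin (Mf) had -1.58, tropomyosin Tm2 -1.46 and troponin I (wupA) -1.37. The control means rest on a few libraries: Mlc2 was at 43.1, 39.1 and 30.5 FPKM in worker GFP replicates 1, 4 and 8, and between 6.38 and 16.63 FPKM in the other 5. For Tm2, replicates 1 and 4 had 41.2 and 43.7 FPKM, and for Mf 21.4 and 29.9 FPKM. Whether muscle was carried over in the dissection was not tested, here or in the later comparisons. The muscle values therefore cannot be assigned to brain cells. Cytosolic ribosomal protein genes were lower as a group, with all 57 members below 0 and a median log2 difference of -0.41, but were not called with an estimated correlation (adjusted p = 0.651). No gene passed the threshold in limma, with 1618 of 9433 genes at an unadjusted p under 0.05, and limma voom on recovered reads also gave 0.

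Of the 24 lists, 5 were called in workers by camera, and none with an estimated correlation (adjusted p = 0.651 for each). Besides muscle (14 measured, median -0.82, adjusted p = 2.17e-06) and cytosolic ribosomal proteins (adjusted p = 3.43e-19), oxidative phosphorylation genes were lower, with 49 of 52 members below 0 and a median of -0.23, or -0.14 without worker Kr-h1 replicate 2. Other detoxification enzymes were also lower (9 of 10 below 0, adjusted p = 0.0176, but from 0.053 to 0.0805 without any of worker GFP replicates 3 and 7 and worker Kr-h1 replicate 2), with Sod1, a superoxide dismutase, at -0.34. Synaptic and neuronal genes were higher as a group, with 41 of 53 members above 0 (adjusted p = 0.000505), among them NLG-5, a neuroligin, at 0.34. Leaving out 1 library at a time, the muscle median was closest to 0 without worker GFP replicate 4 (-0.68, adjusted p = 6.05e-05). Adjusted over the list alone, 6 muscle genes fell, and none of the members of the other 4 lists passed. With the span trend removed, the synaptic list was no longer called (adjusted p = 0.753). Named genes with the smallest p above 0 were anne (0.58), S1P (0.56), Toll-7 (0.52), RhoGAP15B (0.46) and Wdr62 (0.39), none of them past the threshold. Below 0, besides Mlc2 and Mf, they were Ppib (-0.39), the copper transporter Ctr1A (-0.37) and the zinc transporter ZnT86D (-0.26), likewise not past it.

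The second comparison asks the same in gamergates. The receptor tyrosine kinase gene sev (LOC105187874) fell with knockdown, from 11.4 ± 3.79 FPKM (SD, n = 9) to 5.85 ± 1.88 FPKM (SD, n = 8), a log2 change of -0.94 ± 0.19 (SE; limma adjusted p = 0.0252). Hil fell by 1.04 on the log2 scale (adjusted p = 0.0252). Both fng and Ser, genes of Notch signalling, fell, with log2 changes of -0.73 and -0.75 (adjusted p = 0.0451 each). Trs33 (LOC105188572), a subunit of the TRAPP trafficking complex, rose from 5.67 ± 3.27 FPKM (SD, n = 9) to 8.28 ± 4.30 FPKM (SD, n = 8), a log2 change of 0.64 ± 0.11 (SE; adjusted p = 0.0142). In all, 68 genes passed, 30 higher and 38 lower.

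The other named genes that fell were Oatp58Dc, Optix, mwh, Fatp3, wake and Alk, with log2 changes from -0.63 to -0.52. Those that rose were RpL29 (0.71), Tim10, EloC, AP-2sigma, SmD2, mtTFB2, RpS25, Rpb11 and mRpL32 (0.43). Of the 24 lists, 5 were called in gamergates by camera, and none with an estimated correlation (adjusted p from 0.418 to 0.45). Cytosolic ribosomal proteins were among them (adjusted p = 5.36e-16): 57 of 57 members were above 0 with a median of 0.39, 2 members rose over all genes tested, and 41 rose when adjusted over the list alone. For oxidative phosphorylation, 49 of 52 members were above 0 (adjusted p = 2.2e-09). None of its members passed over all genes, while 18 rose and 1 fell adjusted over the list alone. Circadian clock genes were lower as a group (4 measured, adjusted p = 0.00424), with Clk at -0.47 and per at -0.56, and 3 fell adjusted over the list alone. Glial markers (13 measured, adjusted p = 0.00253) had Gat-a at -0.54 and repo at -0.26, and 3 fell adjusted over the list alone. All 5 haemocyte markers were below 0 (adjusted p = 0.04), with Hml at -0.32 and none passing either way. Their call was lost without any of gamergate GFP replicate 3 and gamergate Kr-h1 replicates 2 and 5 (adjusted p from 0.0516 to 0.0861). Photoreceptor and retinal genes were not called by camera (adjusted p = 0.186), with 8 of 9 members below 0 and a median of -0.49. Whether sev and Optix moved with the retinal genes across libraries was not tested. The count of 68 changed to 0 without gamergate GFP replicate 2 and to 866 without gamergate GFP replicate 3, and it moved by over 1.5 times in 27 of the 32 fits that left out 1 library, all but those without worker GFP replicates 5 and 7, gamergate GFP replicates 8 and 9 or worker Kr-h1 replicate 1. It was also 0 with the trend over gene span removed, which ended the calls of glial (adjusted p = 0.0639) and haemocyte markers (0.161).

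The third comparison tests whether the knockdown effect differs between castes. Of 57 cytosolic ribosomal genes 52, and of 52 oxidative phosphorylation genes 30, had a higher effect in gamergates than in workers, while 3 of 4 clock genes and 8 of 53 synaptic genes had a lower one. The adjusted p of these lists lay between 0.398 and 0.485 with an estimated correlation, and with the span trend removed the synaptic median turned to 0.05. RpL29 (LOC105187934) differed by 1.15 ± 0.25 on the log2 scale (SE; limma adjusted p = 0.0155), with 42.9 ± 14.6 FPKM (SD, n = 8) in worker controls against 30.0 ± 5.95 (SD, n = 7) after knockdown, and 15.4 ± 9.02 (SD, n = 9) against 22.2 ± 10.7 (SD, n = 8) in gamergates. Clk (LOC105190712), a core clock transcription factor, differed by -0.91 ± 0.18 (SE; adjusted p = 0.0155). In all, 1554 genes passed, 893 with a higher and 661 with a lower effect in gamergates.

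Among named genes past the threshold, the highest differences were for Rh5 (1.30), UK114, UQCR-6.4 (1.21), RpL29, RpL9, RpS30, Saysd1, RpL28, mRpS21 and Ssb-c31a (1.04). The lowest were for uif (-1.43), Asap, Fur2, yellow-b, BBIP1, nord, the chitin synthase gene kkv (-1.11), Hil, tam and Ppa (-1.09). Of the 24 lists, 10 were called by camera, and none with an estimated correlation (adjusted p from 0.398 to 0.485). Among cytosolic ribosomal proteins 52 of 57 members had a higher effect in gamergates, and 56 adjusted over the list alone. Among oxidative phosphorylation genes 30 of 52 were higher and 1 lower, and 41 and 1 adjusted over the list alone. Detoxification enzymes had 4 of 10 higher, and 4 adjusted over the list alone: Prx5, Prx6a, Tpx-3 and Sod1. Among synaptic and neuronal genes 8 of 53 were lower, and 7 adjusted over the list alone, including the glutamate receptor gene Nmdar1 (-0.46) and NLG-5 (-0.58). Clk, per and cyc were lower among 4 clock genes, and 3 adjusted over the list alone. Insulin and TOR signalling had 3 of 16 lower, and 4 adjusted over the list alone, with chico (-0.50), Tor (-0.68) and InR-2 (-0.44). Biogenic amine genes had 2 of 15 lower, the octopamine receptor genes Oamb (-0.80) and Octalpha2R (-0.96), with 4 lower and 1 higher adjusted over the list alone. Glial markers had 2 of 13 lower, ine and Nrx-IV, and haemocyte markers had 1 of 5 lower, Ppn (-0.77), with 2 and 1 adjusted over the list alone. Muscle was called with no member past the threshold either way, and 13 of its 14 members lay above 0. Its call rests on single libraries: it was lost without gamergate Kr-h1 replicate 2, the library with 57.5 FPKM of Mlc2 (next 10.75), and without any of worker GFP replicates 1, 4 and 8, gamergate GFP replicates 1 and 3 and worker Kr-h1 replicates 4 and 6 (adjusted p from 0.0525 to 0.106). Of 32 fits that left out 1 library, 17 kept the call of biogenic amine genes, 17 that of haemocyte markers and 20 that of insulin and TOR signalling. The glial call was lost without gamergate GFP replicate 3 (adjusted p = 0.0602), and the detoxification call without gamergate GFP replicate 1 (0.0685).

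**Figure D2:**
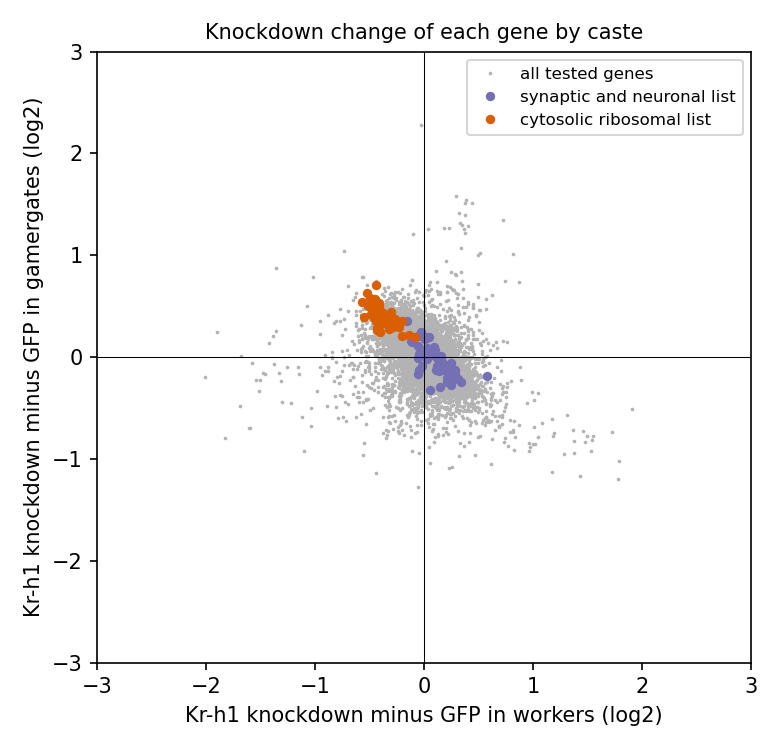
Log2 difference between Kr-h1 knockdown and GFP control for each of 9433 genes in workers (horizontal axis) and gamergates (vertical axis), with 2 gene lists marked. The 57 cytosolic ribosomal genes lie below 0 in workers and above 0 in gamergates; over all genes the Spearman correlation is -0.533, with -0.599 within round 2 and 0.026 within round 3.

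Knockdown effects of the castes were negatively correlated where round 2 workers entered, and no permutation test was run on these correlations. Across genes, which are not independent replicates, the effect in round 2 workers had a Spearman correlation of -0.599 with that in round 2 gamergates and -0.43 with that in round 3 gamergates. For round 3 workers the values were 0.009 and 0.026. Without worker Kr-h1 replicate 2, the values for round 2 workers were -0.43 and -0.267. Gene span moved with these effects. The correlation across genes of each library's log2 deviation with gene span averaged 0.356 ± 0.144 (SD, n = 4) in gamergate GFP and 0.122 ± 0.122 (SD, n = 4) in gamergate Kr-h1 libraries of round 2. In round 3 the means were 0.039 ± 0.131 (SD, n = 5) and -0.227 ± 0.077 (SD, n = 4). In workers they were -0.320 ± 0.101 (SD, n = 5) and -0.108 ± 0.372 (SD, n = 4) in round 2, where worker Kr-h1 replicate 2 was at 0.436 and the mean without it -0.289, and -0.237 ± 0.076 (SD, n = 3) and -0.061 ± 0.081 (SD, n = 3) in round 3. The median span was 1.52 kb for cytosolic ribosomal genes, 1.57 kb for oxidative phosphorylation genes and 44.5 kb for synaptic and neuronal genes. With the span trend removed, 174 genes passed the test of the caste difference, and cytosolic ribosomal proteins (adjusted p = 3.81e-18), oxidative phosphorylation genes (9.33e-06) and muscle (0.00528) were still called. The other 7 lists were not, and the median of insulin and TOR genes turned to 0.01. The count was 399 without worker Kr-h1 replicate 2, 875 without gamergate GFP replicate 1, 778 without gamergate GFP replicate 2, 1009 without worker Kr-h1 replicate 4 and 787 without gamergate Kr-h1 replicate 1. It was 0 without the 4 libraries of low array weight (limma, 1953 at an unadjusted p under 0.05), and 0 in each round alone.

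**Figure D3:**
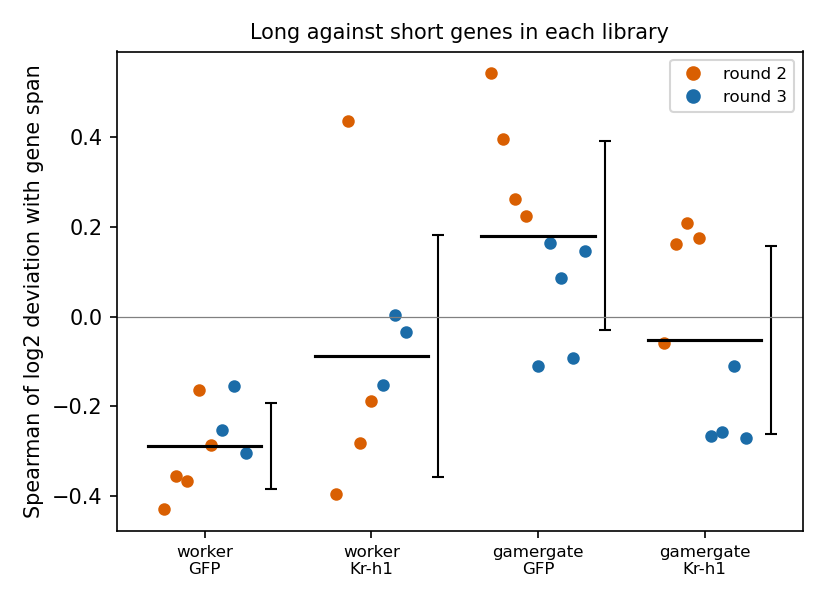
Spearman correlation across genes between a library's log2 deviation from the gene mean and gene span, for each library of the 4 groups, coloured by experiment round; black lines are group means and bars 1 SD. Worker controls all lie below 0, and gamergate controls of round 2 all lie above 0.

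The fourth comparison asks how gamergates differ from workers in GFP controls. With the batch term, castes can be compared only within round 3, which held 3 worker and 5 gamergate controls. The log2 differences also draw on other libraries of both rounds through the shared fit, and are not those of these controls alone. The means given beside the log2 differences pool both rounds, so the 2 need not match. The opsin gene Lop1 (LOC105189783) was lower in gamergates, at 17.3 ± 7.05 FPKM (SD, n = 9) against 101.4 ± 70.4 FPKM (SD, n = 8), a log2 difference of -3.18 ± 0.54 (SE; limma adjusted p = 0.00461). The opsin gene Rh5 (-2.11) and the cuticular protein gene CPR1 (-3.01) were lower too. The insulin-like peptide gene ILP-2 (LOC105188195) was lower in gamergates, at 11.8 ± 2.70 FPKM (SD, n = 9) against 21.6 ± 4.78 FPKM (SD, n = 8), with a log2 difference of -0.89 ± 0.20 (SE; adjusted p = 0.0193). Nmdar1 (LOC105182141) was higher, at 41.8 ± 4.90 FPKM (SD, n = 9) against 23.4 ± 3.25 FPKM (SD, n = 8), with a log2 difference of 0.67 ± 0.11 (SE; adjusted p = 0.00461). In all, 125 genes passed, 69 higher and 56 lower in gamergates.

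Of the 24 lists, 6 were called by camera, and none with an estimated correlation (adjusted p from 0.522 to 0.781). Glial markers were higher in gamergates (adjusted p = 0.00253, and 0.522 with an estimated correlation): of 13 measured, the GABA transporter genes Gat-a (1.03) and Gat-1B (0.74), the glutamate transporter gene Eaat-2 (0.99) and ine (0.52) passed, and 5 passed adjusted over the list alone. Other named genes that were higher were the gap junction genes Inx2 (1.26) and Inx3 (0.87), sev (1.03), Cad74A, dpn, per (0.87) and Tsp5D. Other lower ones were RpL28 (-1.01), RpL37-1, Tim10, RpL31, Ssb-c31a and Dad1 (-0.75). All 57 cytosolic ribosomal genes lay below 0 (adjusted p = 4.35e-22), 5 of them lower over all genes and 47 adjusted over the list alone. Synaptic and neuronal genes were higher as a group (adjusted p = 0.00253), with Nmdar1 and Lcch3 passing and 3 passing adjusted over the list alone. Clock genes (adjusted p = 0.0474) had 1 of 4 members passing, per, and 3 adjusted over the list alone. Sugar metabolism genes (adjusted p = 0.0264) had none of 11 passing over all genes and 2 adjusted over the list alone, with Ald1 at 0.37 and Glyp at 0.50. For oxidative phosphorylation 40 of 52 members were below 0 (adjusted p = 0.0264), with none passing either way. With the span trend removed, the ribosomal list alone was called (adjusted p = 3.22e-19). Leaving out 1 library at a time, the clock call held in 16 of 32 fits. The oxidative phosphorylation call was lost without any of gamergate GFP replicates 1 and 2, worker Kr-h1 replicates 2 and 5 and gamergate Kr-h1 replicates 1 and 8 (adjusted p from 0.0505 to 0.135), and the synaptic call without worker GFP replicate 8 (0.199). The count was 26 without worker GFP replicate 8, 231 without gamergate GFP replicate 3 and 4436 without the batch term. Fitted to the control groups alone, limma called 0 genes, with 744 at an unadjusted p under 0.05, which ends the calls given here. Some sizes held, with Lop1 at -3.09, ILP-2 at -1.07, Nmdar1 at 0.60 and per at 1.00. Others shrank: RpL28 to -0.62, RpL37-1 to -0.55, Tim10 to -0.53, RpL31 to -0.49, Ssb-c31a to -0.50 and Inx2 to 0.90. The count lay between 50 and 83 when any of worker GFP replicates 2, 6 and 7, gamergate GFP replicates 2, 4, 6, 7 and 9, worker Kr-h1 replicates 4, 5, 6 and 7 or gamergate Kr-h1 replicates 3, 5 and 7 was left out.

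**Figure D4:**
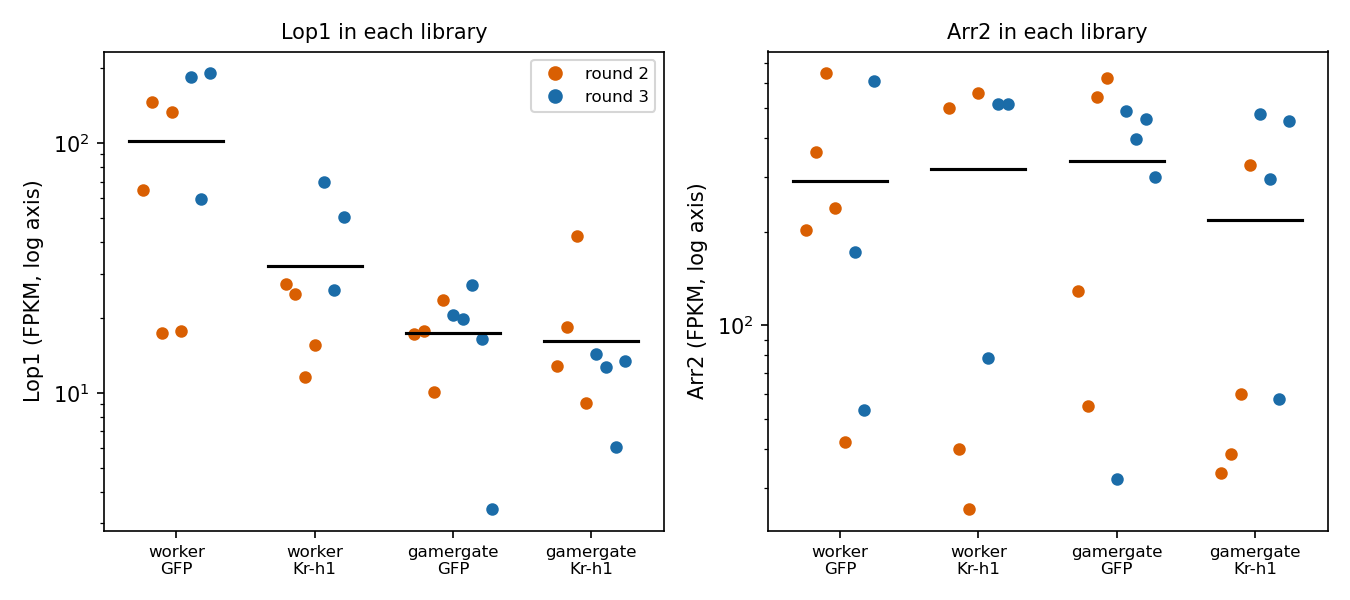
Lop1 and Arr2 in FPKM (log axes) in each library of the 4 groups, coloured by experiment round; black lines are group means. Lop1 is highest in worker controls, up to 189.9 FPKM, and reaches 27.1 FPKM in gamergate controls, while Arr2 spans 25.7 to 646.8 FPKM over the libraries.

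Among knockdown libraries, gamergates had more of the neuropeptide gene CCHa1 (LOC105181279) than workers, at 9.10 ± 2.71 FPKM (SD, n = 8) against 4.62 ± 1.15 FPKM (SD, n = 7), a log2 difference of 1.39 ± 0.23 (SE; limma adjusted p = 0.00841). Here too castes can be compared only within round 3, with 3 worker and 4 gamergate knockdown libraries, while the means pool both rounds. The log2 differences again draw on other libraries of both rounds through the shared fit. Qbp-1 was also higher (1.34). ILP-2 was lower here as well, by -0.95 ± 0.20 (SE; adjusted p = 0.0419), and mol (-2.85) and the DNA polymerase gene DNApol-alpha180 (-0.54) were lower. In all, 16 genes passed, 5 higher and 11 lower. Oxidative phosphorylation genes were higher as a group, with 50 of 52 members above 0 (adjusted p = 7.46e-15, and 0.516 with an estimated correlation). None passed over all genes and 9 adjusted over the list alone, and ATPsynB (0.61), ATPsyngamma (0.42), ATPsyndelta (0.41) and UQCR-C1 (0.50) had the smallest p. Of cytosolic ribosomal genes 56 of 57 were above 0 (adjusted p = 0.000202, and 0.791 with an estimated correlation), with none passing either way, RpL29 at 0.48 and RpL4 at 0.34. RpL29 turned to -0.56 without the batch term. The ribosomal list was not called with the span trend removed (adjusted p = 0.178) or without the 4 libraries of low array weight (0.416), while the oxidative phosphorylation list was called in both fits (1.48e-12 and 5.21e-12). Named genes that did not pass were OSCP1 (0.68), P5CS (-1.15) and ci (-0.61). The count was 2 without any of gamergate GFP replicate 2, worker Kr-h1 replicates 3, 6 and 7, or gamergate Kr-h1 replicate 5, and 71 without gamergate GFP replicate 3. It moved by over 1.5 times in 23 of the 32 fits that left out 1 library, all but those without worker GFP replicates 1, 4, 5 and 6, gamergate GFP replicate 4, worker Kr-h1 replicate 1 or gamergate Kr-h1 replicates 2, 3 and 6. Fitted to the knockdown groups alone, limma called 0 genes, with 726 at an unadjusted p under 0.05, which ends the calls of CCHa1 (1.09), ILP-2 (-0.77) and mol (-2.59). In round 2 alone, DNApol-alpha180 was at 0.16 and ci at 0.14.

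Averaged over both castes, the lowest p among named genes belonged to bnb (LOC105189268), with 314.9 ± 170.1 FPKM (SD, n = 8) in worker controls and 190.0 ± 21.7 (SD, n = 7) after knockdown, and 381.8 ± 51.5 (SD, n = 9) and 263.6 ± 57.8 (SD, n = 8) in gamergates. Its mean log2 difference was -0.57 ± 0.12 (SE; limma adjusted p = 0.193). Mtp, fng, Pdk and Dll had differences from -0.53 to -0.31, and Phyhd1, mal, Hydr2, fwd and tty from 0.31 to 0.70, none past the threshold. No gene passed in limma, with 583 at an unadjusted p under 0.05, and limma voom on recovered reads also gave 0. Without worker Kr-h1 replicate 2, 36 genes passed, and 1 or 2 without any of worker GFP replicates 1, 3 and 5, gamergate GFP replicate 9 or gamergate Kr-h1 replicates 5 and 7. Without the 4 libraries of low array weight, 62 passed. Muscle genes were lower as a group (13 of 14 below 0, median -0.51, adjusted p = 2.38e-08, and 0.429 with an estimated correlation), with TpnT at -0.86 and 5 members that fell adjusted over the list alone. Besides worker GFP replicates 1 and 4, with 41.2 and 43.7 FPKM of Tm2, gamergate Kr-h1 replicate 2 was high in muscle genes, at 57.5 FPKM of Mlc2 (next 10.75) and 69.7 FPKM of Tm2 (next 11.4). The muscle median was -0.67 without that library and -0.42 without worker GFP replicate 4 (adjusted p = 1.56e-05, the highest of 32 such fits). Glial markers (adjusted p = 0.0243, e at -0.28) and cuticle and chitin proteins (adjusted p = 0.0243, CPR14 at -0.60) were also called, with no member passing either way, and held in 24 and 21 of 32 fits that left out 1 library. With an estimated correlation, the adjusted p of these lists lay between 0.429 and 0.58.

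The last comparison followed caste-biased genes into the knockdown. The lists were the 200 genes at each end of the ranking by moderated t for gamergate against worker in round 3 controls. They are ranks and not called genes: limma fitted to the control groups alone called 0 genes. The 200 worker-high genes had a median log2 change of -0.26 with knockdown in round 2 workers (exact two-sided permutation p = 0.00794, the smallest that 126 splits can give, adjusted over 4 tests 0.0317), and 158 of them were lower. The 200 gamergate-high genes had a median of -0.22 in round 2 gamergates (exact p = 0.0286, the smallest that 70 splits can give, adjusted 0.0571), and 151 were lower. Worker-high genes in gamergates had a median of 0.25 (exact p = 0.114), and gamergate-high genes in workers 0.09 (exact p = 0.19). Across genes, which are not independent replicates, the knockdown effect of round 2 had a correlation with gene span of 0.333 in workers (0.159 without worker Kr-h1 replicate 2) and -0.485 in gamergates, and the 4 libraries of low array weight all belong to round 2. With the span trend removed, the worker-high median in workers was -0.16 (exact p = 0.0238) and the gamergate-high median in gamergates -0.13 (exact p = 0.114). Without the low-weight libraries they were -0.15 (exact p = 0.0286, the smallest that 35 splits can give) and -0.19 (exact p = 0.10, the smallest that 20 splits can give). With lists from round 2 and changes from round 3, the worker-high median in workers was -0.07 (exact p = 0.40, where 20 splits cannot give less than 0.1), and the gamergate-high median in workers turned to -0.09 (exact p = 0.10). In gamergates this exchange gave -0.26 for gamergate-high genes (exact p = 0.0238, 194 of 200 lower) and 0.27 for worker-high genes (exact p = 0.0238, 198 of 200 higher). Lists from round 2 mix caste with sequencing run, since round 2 gamergates were alone on run 200508.

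In the fixed panel, 3 genes differed between castes in their knockdown effect. The ecdysone-response gene br averaged 6.25 ± 2.66 FPKM (SD, n = 9) in gamergate controls and 4.39 ± 1.28 (SD, n = 8) after knockdown, against 2.83 ± 1.59 (SD, n = 8) and 4.42 ± 1.98 (SD, n = 7) in workers, a difference of -1.02 ± 0.30 (SE; limma adjusted p = 0.0261). The neprilysin gene Nep3 differed by -0.80 (adjusted p = 0.0231) and the nuclear receptor gene ftz-f1 by -0.46 (adjusted p = 0.0374). None of these calls held without the 4 libraries of low array weight, where no gene passed. Gamergate GFP replicate 1, 1 of those libraries, was far above its group for br (12.94 FPKM, next 7.40) and Nep3 (46.3 FPKM, next 30.5). Corazonin (Crz) averaged 33.0 ± 17.1 FPKM (SD, n = 8) in worker and 39.4 ± 6.97 FPKM (SD, n = 9) in gamergate controls over both rounds. Its log2 caste difference with the batch term, from the shared fit that compares castes within round 3, was 0.76 ± 0.29 (SE; limma adjusted p = 0.14). Eip93F, Ecr, usp and Nep2 passed in no comparison. Nep5 and the odorant receptor coreceptor gene Orco lay below the filter, and Orco averaged 0.015 FPKM or less in each group.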

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

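The tests with the span trend removed, of discordant libraries, of the repeat between rounds, of the sequencing run and of Lop1 and Rh5 against other retinal genes were chosen after the results were seen. In 12 of 56 group measures, 1 library stood apart from its group by Dixon's test. Its chance rate of about 1 in 20 holds for normally distributed values. The values tested were not log-transformed, so the share cannot be set against that rate. The 12 measures came from 8 libraries. Gamergate GFP replicate 1 was highest in its group for Kr-h1 (7.57 FPKM, next 2.79), br (12.94 FPKM, next 7.40), Nep2 (22.8 FPKM, next 6.14) and Nep3 (46.3 FPKM, next 30.5). Kr-h1 also stood apart in worker GFP replicate 4 (2.54 FPKM, next 1.02) and worker Kr-h1 replicate 4 (0.840 FPKM, next 0.435). The gene usp stood apart in gamergate Kr-h1 replicate 7 (43.5 FPKM, next 33.9). Orco was listed above 0 in a single library of each knockdown group, worker Kr-h1 replicate 3 (0.0416 FPKM) and gamergate Kr-h1 replicate 4 (0.0299 FPKM). With all other values of a group at 0, any value above it stands apart. Worker Kr-h1 replicate 6 had the most recovered reads of its group (12.95 M), and low genes were at 0 more often than in the rest of their own groups in worker Kr-h1 replicate 4 (9.73%) and gamergate Kr-h1 replicate 6 (15.2%).

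The knockdown effect differed between castes at 1554 genes by an interaction test, with ribosomal genes such as RpL29 and RpS25 on one side and Clk, Tor and Nmdar1 on the other. Among 100 splits of the libraries within batches, only the real split gave as many, and the highest other gave 0. A share of 1 of 100 is the smallest these splits can give. They shuffle treatment in both castes, so they test for no knockdown effect in either caste, not for an equal effect in both. Gene length bias may account for most of the count, as 174 genes were left with the span trend removed. That step would also remove a real difference between short ribosomal and long synaptic genes, so it cannot tell these apart. A few discordant libraries may also account for the count, as 0 genes were left without the 4 libraries of low array weight. Leaving them out also removes power. A caste difference in the response also stays open: the difference in round 2 correlated with that in round 3 across genes (Spearman 0.397, exact permutation p = 0.0357 over 2520 splits), and 0.23 with the span trend removed (exact p = 0.173). These splits also shuffle treatment, so their p does not test for an equal effect in both castes. The repeat rests on gamergates, whose effect had a correlation of 0.574 between rounds against 0.028 in workers. Effects of the castes were negatively correlated where round 2 workers entered (-0.599 with round 2 and -0.43 with round 3 gamergates). For round 3 workers the values were 0.009 and 0.026. No permutation test was run on the correlations within and between castes.

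Without the batch term, 4436 genes differed between castes in controls. A difference between sequencing runs is a candidate explanation: rounds 2 and 3 differed at 4768 genes in gamergates, whose rounds were on different runs, and at 210 in workers, whose rounds shared a run. Caste differences that exist only in round 2 cannot be told apart from the run, because round 2 gamergates had a run of their own.

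Among 9 retinal genes, Lop1 and Rh5 were lower in gamergate controls, while the other 7 lay above 0, so that the list as a whole was not lower (median 0.616). The amount of eye tissue may vary between brains, since the residuals of the 9 genes had a median pairwise correlation of 0.551, and 0.95 among the other 7. In these controls, the mean of Lop1 and Rh5 minus the mean of the other 7 differed between castes by -3.456 (SE 0.881). Lop1 and Rh5 were singled out for being lower in the same libraries, so this value is not a test. It cannot decide on carried-over eye tissue as a whole, or on a caste difference of like size in all 9 genes. Under knockdown, Lop1 had a log2 caste difference of -1.86 (limma adjusted p = 0.121) and Rh5 one of -0.80 (limma adjusted p = 0.362). In knockdown libraries the list had a median log2 difference of -0.115, which decides nothing by itself. A caste difference limited to Lop1 and Rh5, or tissue that holds these opsins without the others, stays open: across libraries, the residuals of Lop1 and Rh5 had a correlation of 0.677 with each other and a median of -0.039 with the other 7, which does not separate these.

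For the remaining counts above 0, no other split gave as many as the real one. This held in gamergate knockdown (68 genes against at most 3 in the other splits, 1 of 100 as large), in caste among controls (125 against at most 1, 1 of 56) and in caste under knockdown (16 against at most 3, 1 of 35). These are the smallest shares that so many splits can give, and they were not adjusted over the comparisons. They make chance less likely but do not exclude it. For the counts of 0 in workers and in the average effect, all 100 splits give at least as many by construction, so the splits say nothing about chance there. The highest other splits gave 2 and 159 genes, and a structure of the samples behind the split with 159 genes was not identified.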

How the results depend on the processing

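Fits to round 2, without low-complexity or low-weight libraries, with the span trend removed and by voom, and those of the called lists and of the correlations between effects without each library, were chosen after seeing the data. Except where the change drops samples or loosens a threshold, the cause was not tested. In workers, 0 genes passed except with run 200626 only (1) and array weights (5). The pseudocount, the median-of-ratios scaling and the robust variance model left each count within 1.5 times.

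For gamergate knockdown (68 genes), the count was 835 at an adjusted p under 0.10, 11 with no filter, 40 with quantile normalization, 0 with no batch term, 2 with batch as round only, 0 with run 200626 only, 6 with round 3 only, 11 with round 2 only, 179 with only the groups compared, 820 with array weights, 368 without low-complexity and 144 without low-weight libraries, 0 with the span trend removed and 38 with voom. For the caste difference of the knockdown effect (1554), it was 2677 at an adjusted p under 0.10, 0 with no batch term, 1 with batch as round only, 0 with run 200626, round 3 or round 2 only, 817 with array weights, 620 without low-complexity and 0 without low-weight libraries, and 174 with the span trend removed, of which 147 were among the 1554.

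For caste in controls (125), the count was 556 at an adjusted p under 0.10, 81 with no filter, 235 with quantile normalization, 4436 with no batch term, 4878 with batch as round only, 56 with round 3 only, 5118 with round 2 only, 0 with only the groups compared, 1106 with array weights and 286 without low-weight libraries. For caste under knockdown (16), it was 85 at an adjusted p under 0.10, 6 with no filter, 35 with quantile normalization, 813 with batch as round only, 6 with run 200626 only, 69 with round 3 only, 2147 with round 2 only, 0 with only the groups compared, 395 with array weights, 25 without low-complexity and 31 without low-weight libraries, and 34 with the span trend removed. For the average effect (0), it was 2 at an adjusted p under 0.10, 2 with a mean FPKM of at least 5, 1 with round 3 only, 92 with array weights and 62 without low-weight libraries.

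With the replicate number as a block, the counts were 113 for gamergate knockdown, 698 for the caste difference of the effect, 53 for caste in controls, 3 for caste under knockdown and 6 for the average. The numbers did not pair the samples: 11 of 26 same-number pairs had a residual correlation over 0.1, with a median of -0.071 against -0.054 for other pairs.

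Leaving out 1 library at a time, the counts ranged from 0 to 0 in workers, 0 to 866 in gamergates, 399 to 2191 for the difference, 26 to 231 for caste in controls, 2 to 71 for caste under knockdown and 0 to 36 for the average. Kr-h1 ranged from -0.58 to -0.32 in workers by either test, and in gamergates from -1.08 to -0.70 by the exact test and -1.13 to -0.76 by limma. Among these fits, limma's unadjusted p in workers was under 0.05 only without gamergate GFP replicate 1, at -0.48.

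For Kr-h1 in workers, the exact test missed 0.05 with round 3 only (-0.30), round 2 only (-0.60), without low-weight (-0.32, exact p = 0.081) and without low-complexity libraries (-0.25, exact p = 0.118). In gamergates it missed it with round 3 only (-0.32) and round 2 only (-1.79). With run 200626 only, limma's unadjusted p was under 0.05 in workers (-0.48) and not in gamergates (-0.32). Kr-h1 has no value with a mean FPKM of at least 5.

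For gamergate-high genes in gamergates, the median was -0.20 with lists of 100 genes (exact p = 0.0571), and in workers 0.10 with lists of 500 (exact p = 0.0317). With lists from round 2 and changes from round 3, gamergate-high genes in workers reversed to -0.091 and worker-high genes in workers were at -0.074, while in gamergates the medians were -0.26 for gamergate-high (exact p = 0.0238, 194 lower) and 0.27 for worker-high genes (exact p = 0.0238). For gamergate-high genes in gamergates, the median was -0.13 with the span trend removed (exact p = 0.114) and -0.19 without low-weight libraries (exact p = 0.10, the smallest that 20 splits can give). With all libraries for both, the medians were 0.25, -0.30, -0.27 and 0.31 for gamergate-high and worker-high genes in workers and then in gamergates, against 0.15, -0.15, -0.14 and 0.13 in 20 simulations of unchanged groups that share these controls. The simulations held no batch difference and noise independent between genes, while the real lists mix caste with sequencing run. The simulated medians therefore show only the pull of shared controls, and the gap to the real medians decides nothing.

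With an estimated correlation 0 lists were called in each of the 6 comparisons. With the span trend removed, 3 were called in gamergates, 3 for the difference, 1 for caste in controls and 1 under knockdown. Without low-weight libraries, 5 were called for the difference, 1 for caste under knockdown and 5 for the average. With no batch term, 4 were called for caste under knockdown. Among named genes, cwo in controls reversed to 0.038 with no batch term, 0.013 with batch as round only and 0.10 with round 2 only. Under knockdown, RpL29 reversed to -0.56, -0.61 and -1.23 in these fits, and with round 2 only DNApol-alpha180 reversed to 0.16 and ci to 0.14. Of the other values of named genes, 2854 kept their direction and side of the threshold, 658 no longer passed and 116 passed only in the alternative. Depth limits genes near the filter, such as Kr-h1 with 4 to 362 reads.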

Other observations

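Some genes had very wide ranges between single brains. An unnamed gene, LOC112588745, ranged from 101.4 to 43675.8 FPKM, apd-3l from 34.5 to 34816.3 FPKM, LOC105189843 from 41.5 to 31527.1 FPKM and LOC105189844 from 21.1 to 15900.5 FPKM. They were the 4 genes with the widest ranges, chosen after their values were seen. Whether these genes varied with each other or with the retinal genes across libraries was not tested. The retinal gene Arr2 ranged from 25.7 to 646.8 FPKM over the libraries.

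Among lists that camera did not call in any comparison, juvenile hormone and ecdysone genes (15 measured) had 2 members with a lower knockdown effect in gamergates than in workers, and Kenyon cell markers (12 measured) also had 2. Neuropeptide genes (14 measured) held ILP-2, lower in gamergates, and CCHa1, higher in gamergates under knockdown. All 5 immediate-early genes lay below 0 in gamergates against workers under knockdown, with a median of -0.39 (camera adjusted p = 0.0726). Fat body and haemolymph storage genes (8 measured) and odorant-binding and chemosensory genes (7 measured) had no member past the threshold in any comparison.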
